A study of Mus musculus with 12 samples.

How the data were processed

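Poly(A) RNA of 12 libraries was sequenced in 4 groups of 3 (PBS, PZH, aPD1 and PZH_aPD1). Per the labels' protocols, RNA was extracted with TRIzol, 1 µg with an RNA integrity number above 7 entered each library, and the NEBNext Ultra kit was used with fragments of about 200 bp. The labels call the tissue mouse colon and the cells epithelial, while the design text describes subcutaneous MC38 tumours, so the libraries are taken here as RNA of whole tumour samples, whose cell makeup no label gives. The submitters' processing notes list FastQC 0.11.5, HISAT2 2.1.0, StringTie 1.3.3b and DESeq 1.28.0 without saying what each did. The genome build, the annotation and the program that counted reads are not given in the sources used here, so no coordinates are printed.

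The deposited table holds raw counts, whole numbers per gene and library that the authors did not normalize, as its differing column totals (14941535 to 19957441) show. Its 56628 entries are 55416 Ensembl identifiers and 1212 assembled loci with XLOC names. GENCODE M21 gave symbols for 52083 of the Ensembl identifiers and none for 3333. Columns were matched to samples by name: the stems for control and PZH match the labels, and AP and COM were read as abbreviations of the anti-PD-1 and the combination arm, a reading that no label spells out. Counting is not stated to use strand, so overlapping and antisense genes, and near-identical paralogs such as the haemoglobin genes, carry some uncertainty.

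Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes passing edgeR's filter by group (minimum count 10) numbered 16885, of which 364 were XLOC loci. Libraries were scaled by TMM, and edgeR's robust quasi-likelihood test was fitted on all 12 libraries with 1 mean per group and no covariate (8 residual degrees of freedom, common biological coefficient of variation 0.468). Contrasts were the 6 pairs of groups, the interaction of PZH and aPD1, and a test of any difference among the 4 groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. CPM values are counts scaled by the library total (edgeR's CPM) with TMM factors and are given as mean ± SD over 3 libraries, and log2 fold changes with their SE. The labels, the design, the alternatives and all gene lists were fixed before the data were examined, except where the text says that a choice was made after seeing them.

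Gene lists numbered 32 (tumour, immune, stromal and neighbouring tissue cell types, signalling pathways and metabolic programmes), of which 31 had at least 5 tested members. The colon mucosa list had 2 of 21 members tested and got no test. Lists were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a contrast. For each list the members passing are counted over all genes tested and adjusted over the list alone.

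Genes are named by a fixed rule. Named are the genes of the study's title (Cd274, Stat3 and 11 stem cell genes), then per contrast the 6 largest changes in each direction and the 3 smallest p values in each direction among called genes with an average log2 CPM of at least 1, no overlap between the 2 groups and no predicted-gene symbol. Where no gene met these conditions, the 5 genes with the smallest p are named. Of each list described, the 4 members with the smallest p are eligible. Ddx3y, Hmga2, Krt14, Adipoq, the liver genes, and Pf4 and Gm36377 in aPD1 against PBS, were chosen after their values were seen.

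The 12 pairs of libraries within groups differed by a chi-square per degree of freedom of 25.7 to 312, so none is the same library sequenced again. This does not show whether 2 libraries came from the same tumour. The 10 most abundant genes took 6.39% to 12.1% of a library's counts. The principal components used log2 CPM with a prior count of 2.

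The steps were tested on simulated counts drawn from the real means, library sizes and spread, with 200 genes changed. For changes of 2, 4 and 8 fold, edgeR recovered 2.99%, 46.3% and 68.2% of changed genes in PZH against PBS, 0%, 31.3% and 62.1% in aPD1 against PBS, 0%, 34.3% and 63.6% in PZH_aPD1 against PBS, 1.49%, 31.3% and 72.7% in PZH_aPD1 against aPD1, 2.99%, 34.3% and 50% in PZH_aPD1 against PZH, 2.99%, 53.7% and 66.7% in aPD1 against PZH, and 0%, 2.99% and 34.8% for the interaction. False calls by edgeR were 1 to 7 of 16665 unchanged genes. In PZH against PBS, DESeq2 recovered 14.9%, 65.7% and 81.8% with 56 false calls, and limma-voom 1.49%, 46.3% and 65.2% with 5. A list of 20 genes shifted 2 fold was called by camera in every contrast, except for the interaction with an estimated correlation, and 0 of 30 unshifted lists were called. The simulated genes were drawn independently, so this does not show how often a list of correlated genes is recovered with an estimated correlation. Nor does it show how often such a list is called falsely with the preset correlation. With the real counts, other splits of the libraries called 9 to 23 lists in PZH against PBS and 5 to 19 in aPD1 against PBS. Each of these splits mixes the groups unevenly and so keeps part of any real difference. Their calls are therefore not a count of false calls. With this spread between libraries, changes of 2 fold in single genes were therefore mostly not detectable.

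Alternatives were DESeq2's size factors, no low-count filter, DESeq2 (default independent filtering, adjusted p left missing for 34 genes in each pairwise contrast, 1343 in the interaction and 362 in the test of any group), limma-voom with sample weights, the replicate number as a block, only the 6 libraries compared, a fold minimum of 2, each replicate left out in turn, and camera with an estimated correlation. The sample weights ran from 0.167 (aPD1 replicate 3) to 6.13 (PZH_aPD1 replicate 1), so limma-voom leaned on single libraries. Alternatives added after seeing the data were a fit without the 3 libraries apart on the first principal component and a fit with the mean log2 CPM of 4 Y-linked genes (Ddx3y, Uty, Kdm5d and Eif2s3y) as a covariate. That mean ran from 2.37 to 3.59 in PBS, 4.28 to 5.47 in PZH, 4.22 to 6.07 in aPD1 and 3.48 to 5.40 in PZH_aPD1. It did not overlap between PBS and either single treatment. In those comparisons its effect can barely be told apart from treatment, and adjusted changes are extrapolations.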

Results

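Gene expression was measured by poly(A) RNA sequencing in 12 libraries from mice carrying subcutaneous tumours of MC38, a mouse colon carcinoma cell line. The 4 groups of 3 libraries each had received PBS as vehicle, Pien Tze Huang (PZH, a traditional Chinese medicine formula) for 2 weeks, an antibody against the immune checkpoint receptor PD-1 (aPD1), or both (PZH_aPD1). Total counts per library ran from 14941535 to 19957441, and 16885 genes had enough counts to be tested. The labels do not say that the 3 libraries of a group come from separate mice, so p-values measure the spread between these libraries, which may be technical. The 3 PBS libraries serve every comparison with PBS, so those comparisons share their chance values.

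The libraries of a group differed widely in genes that mark particular cell types. On the first principal component, which held 66.4% of the variance among the 500 most variable genes, PZH replicate 2, aPD1 replicate 3 and PZH_aPD1 replicate 3 lay at 54.3, 65.9 and 66.5, and the other 9 libraries lay between -54.0 and -0.17. In those 3 libraries Hmga2, an oncofetal chromatin protein gene, was at 5.19, 3.15 and 0.94 CPM (counts scaled by library total), against 281 to 307 CPM in the PBS libraries. Krt14, a basal keratin gene, was at or under 1.283 CPM there, against 215 to 367 CPM in PBS. The Y-linked gene Ddx3y stood at 90.3, 146 and 98.8 CPM in the same 3 libraries, at 24.6 to 56.4 CPM in the other 6 treated libraries and at 11.9 to 29.6 CPM in PBS. Adipoq, a hormone gene of fat cells, reached 515 CPM in PZH_aPD1 replicate 3.

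**Figure D1:**
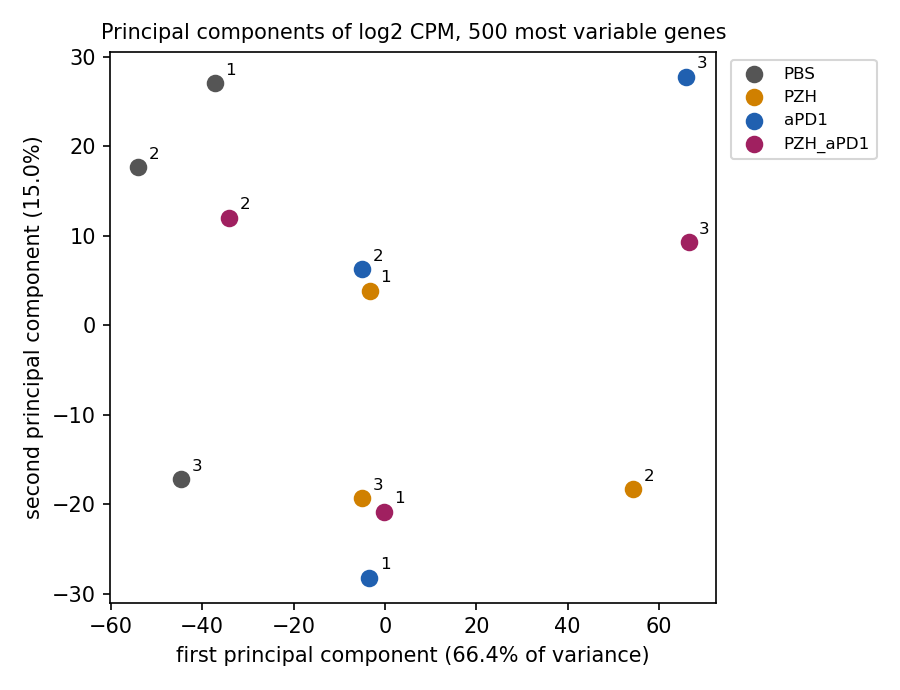
Principal components of log2 CPM over the 500 most variable tested genes, with the first (66.4% of variance) on the x axis and the second (14.96%) on the y axis; each point is a library, coloured by group and numbered by replicate. PZH replicate 2, aPD1 replicate 3 and PZH_aPD1 replicate 3 sit at 54.3 to 66.5 on the first component and the other 9 libraries at or below -0.17.

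The comparison of PZH with PBS asks what PZH alone did in the tumours, and the title of the study names PD-L1, stem cell markers and STAT3. As groups, genes of skeletal muscle, macrophages, neutrophils and other immune cells were higher in the PZH libraries, and genes of cell division and of sterol synthesis were lower, by camera with its preset correlation. With an estimated correlation no list was called (smallest adjusted p 0.343). Stat3 was at 170 ± 28.8 CPM with PZH and 84.0 ± 10.3 CPM with PBS (SD, n = 3 each), and Cd274, which encodes PD-L1, at 119 ± 72.6 and 35.4 ± 11.96 CPM, but no single gene passed the test. edgeR called 0 of 16885 genes, with 4028 at an unadjusted p under 0.05 (844 expected if no gene changed and p-values spread evenly) and a smallest adjusted p of 0.0924. The 5 smallest p values belonged to 1500015O10Rik, H19, Ccn5, Pf4 and Cd300ld3, each higher with PZH (adjusted p 0.0924 each). H19 was at 316 ± 90.5 against 29.5 ± 6.69 CPM and Pf4 at 218 ± 31.3 against 62.1 ± 13.5 CPM. DESeq2 called 2020 genes (1669 higher, 351 lower), limma-voom with sample weights 2153 (1510 higher, 643 lower) and edgeR without the low-count filter 339 (327 higher, 12 lower). With the 3 libraries apart on the first component left out, an alternative added after seeing the data, edgeR called 950 genes (790 higher, 160 lower), and without PZH replicate 3 it called 1.

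Of the title's genes, Stat3, a transcription factor activated by interleukin 6 family cytokines, had a log2 fold change of 1.02 ± 0.23 (SE, edgeR adjusted p 0.0924), and all 3 PZH libraries lay above all 3 PBS libraries. For Cd274 it was 1.75 ± 0.59 (adjusted p 0.129), with PZH libraries at 36.2, 149 and 172 CPM and PBS libraries at 24.6 to 48.3 CPM. DESeq2 called both genes, at adjusted p 0.001403 for Stat3 and 0.0323 for Cd274. In the simulation of this comparison DESeq2 made 56 false calls, against 7 by edgeR and 5 by limma-voom, so its calls weigh less. That simulation was a single draw that used edgeR's own estimates of the spread. limma-voom with sample weights called Stat3 (0.0167) but not Cd274 (0.0952). edgeR called Stat3 without the low-count filter (0.0466) and without the 3 libraries apart (0.0263). Over all alternatives the adjusted p ran from 0.001403 to 0.356 for Stat3 and from 0.0323 to 0.424 for Cd274. The mean of the Y-linked genes as a covariate, added after seeing the data, lowered the log2 fold change of Stat3 to 0.51. The stem cell genes did not move together. Cd44, a surface glycoprotein gene, was at 346 ± 153 CPM against 600 ± 24.8. The transcription factor genes were lower too, with Sox9 at 75.9 ± 58.1 against 216 ± 33.1, Myc at 72.0 ± 50.9 against 139 ± 18.2, Sox2 at 3.58 ± 3.08 against 14.9 ± 4.998 and Klf4 at 129 ± 8.94 against 209 ± 34.3. Aldh1a1, an aldehyde dehydrogenase gene, went the other way, at 53.9 ± 30.1 against 4.99 ± 3.23. In each of these 6 the groups did not overlap, which chance gives in 10% of genes with 3 libraries against 3. Their edgeR adjusted p ran from 0.1102 to 0.507. Aldh1a1 was called by DESeq2 (0.00525), limma-voom with sample weights (0.0240) and edgeR without the 3 libraries apart (0.0475). The Y-linked covariate lowered its log2 fold change from 3.43 to 0.75. Lgr5 and Epcam stayed under 1.5 CPM in every library, Prom1 and Nanog were too low to test, and Pou5f1 had 0 counts. With the same covariate the log2 fold changes of Cd44 (-0.79), Sox9 (-1.51), Myc (-0.95) and Sox2 (-2.05) turned to 0.39, 1.29, 1.54 and 1.44, none of them called. The covariate did not overlap between PZH and PBS libraries, so values adjusted for it are extrapolations that cannot part it from treatment.

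Of 31 gene lists tested by camera with its preset correlation, 22 were called (18 higher, 4 lower). None was called with an estimated correlation, and no member of any list passed over all genes tested. The skeletal muscle list had a median log2 fold change of 3.24, with 21 of 21 members positive and 17 passing adjusted over the list alone (camera adjusted p 1.05e-12; adjusted p = 0.343 with an estimated correlation). Its members included Mb, the gene of myoglobin, at 68.1 ± 24.9 against 7.23 ± 3.18 CPM, and Myl1, a fast myosin light chain gene, at 378 ± 206 against 30.5 ± 19.9 CPM. The macrophage and monocyte list (median 1.83, 17 of 25 adjusted over the list alone, camera adjusted p 1.56e-09; adjusted p = 0.343 with an estimated correlation) included the complement gene C1qc at 907 ± 495 against 209 ± 45.9 CPM and Cd68 at 244 ± 112 against 64.6 ± 16.1 CPM. The neutrophil list had a median of 2.29, with 2 of 19 members, Csf3r and Cxcr2, passing adjusted over the list alone (camera adjusted p 4.36e-06; adjusted p = 0.343 with an estimated correlation). Cxcr2, a chemokine receptor gene, was at 7.15 ± 3.43 against 0.859 ± 0.241 CPM. The T cell list was positive in 24 of 25 members with a median of 1.09, and 0 passed adjusted over the list alone (camera adjusted p 3.94e-05; adjusted p = 0.523 with an estimated correlation). Its member Cd4, the helper T cell coreceptor gene, was at 20.8 ± 7.97 against 2.62 ± 2.65 CPM. The Y-linked gene Ddx3y, at 46.5 to 90.3 CPM with PZH and 11.9 to 29.6 CPM with PBS, and Hmga2, at 5.19 to 213 and 281 to 307 CPM, differed alongside these lists.

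In the same comparison the checkpoint list was higher (median 1.19, 6 of 19 adjusted over the list alone, camera adjusted p 0.000198; adjusted p = 0.343 with an estimated correlation). Its 6 members were Cd274, Pdcd1lg2, Cd80, Lgals9, Vsir and Entpd1, the last a gene of an enzyme that breaks down extracellular ATP, at 109 ± 42.8 against 28.8 ± 10.9 CPM. The list of the STAT3 pathway and its targets was higher too (median 0.64, 11 of 31 adjusted over the list alone, camera adjusted p 0.000162; adjusted p = 0.343 with an estimated correlation), with the adhesion gene Icam1 at 42.6 ± 17.9 against 10.8 ± 3.14 CPM. Proliferation genes were negative in 30 of 30 members (median -1.08, 0 adjusted over the list alone, camera adjusted p 2.82e-05; adjusted p = 0.554 with an estimated correlation), with Mki67 at 93.3 ± 60.3 against 315 ± 54.7 CPM. The sterol and fatty acid synthesis list was lower (median -1.53, 7 of 23 adjusted over the list alone, camera adjusted p 1.94e-08; adjusted p = 0.343 with an estimated correlation), with the desaturase gene Scd2 at 152 ± 45.5 against 473 ± 64.9 CPM. With the Y-linked covariate 11 lists were called, the checkpoint (adjusted p 0.346), T cell (0.473) and sterol (0.255) calls ended, and the proliferation list turned higher (1.02e-10). These outcomes are extrapolations too, since the covariate did not overlap between PZH and PBS libraries.

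The other called lists were those of interferon response (median 0.76), antigen presentation (0.79), fibroblast and matrix (1.43), dendritic cell (1.29) and chemokine and inflammatory cytokine genes (1.33). They were also those of B and plasma cell (1.67), erythroid (2.80), cytotoxic effector and NK (0.83), endothelium (0.50), regulatory T cell (0.76), adipocyte (1.74) and Nrf2 and xenobiotic response genes (0.45). Ribosomal protein (-0.54) and hypoxia and glycolysis genes (-0.73) were called lower. Their smallest adjusted p was 0.343 with an estimated correlation. Lists not called were those of immediate early and dissociation stress (0.65), unfolded protein and heat shock (-0.49), p53 and apoptosis (0.37), epithelial tumour cell (0.44), oxidative phosphorylation (-0.01) and skin keratinocyte genes (-0.10). The cancer stem cell list (median -0.28, mean 0.17, camera adjusted p 0.734), the Wnt target list (-0.79, 0.19 and 0.792) and the epithelial-mesenchymal transition list (-0.16, 0.01 and 0.833) were not called either, and their median and mean differed in sign. The Y-linked covariate turned the adipocyte list lower (3.71e-08) and the hypoxia and glycolysis list higher (0.0001255), and turned the fibroblast (0.499) and B and plasma cell (0.255) lists without a call. Without single libraries some of these calls ended. For the cytotoxic list the adjusted p was 0.105 without PBS replicate 3 and 0.131 without PZH replicate 2. For the regulatory T cell list it was 0.0792, 0.0598 and 0.0887 without PBS replicates 2 and 3 and PZH replicate 3. For the endothelium list it was 0.130 without PBS replicate 2 and 0.0744 without PZH replicate 3. For the adipocyte list it was 0.0659, 0.102 and 0.0571 without PBS replicates 2 and 3 and PZH replicate 1, and for the Nrf2 list 0.0824 and 0.0886 without PBS replicate 2 and PZH replicate 3.

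**Figure D2:**
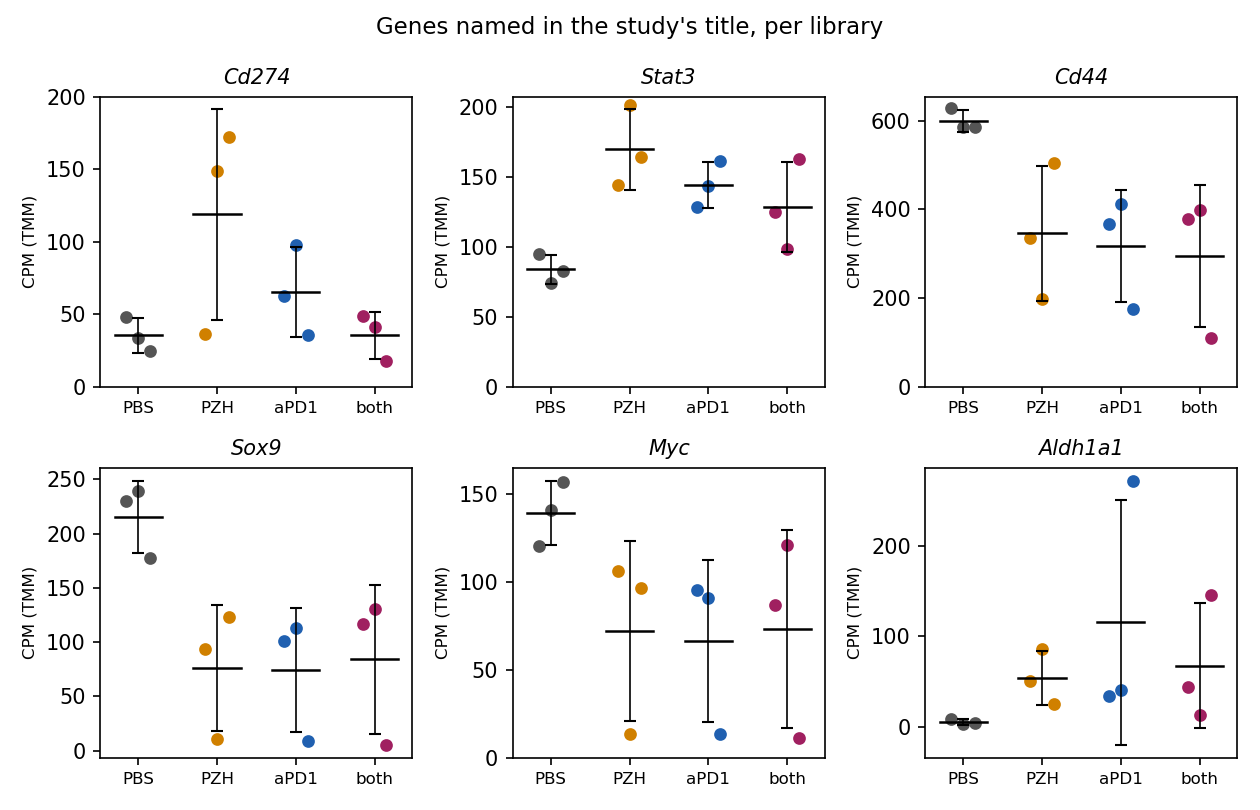
CPM (y axis, TMM scaled) of 6 genes named in or implied by the study's title in each of the 4 groups (x axis; "both" is PZH_aPD1); each point is a library, with the group mean as a line and its SD as error bars (n = 3). All treated libraries lie above all PBS libraries for Stat3, and Cd274 with PZH spans 36.2 to 172 CPM.

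The comparison of aPD1 with PBS asks what the antibody alone did. By edgeR 25 single genes rose and 0 fell (4387 genes at an unadjusted p under 0.05). As groups, genes of muscle and of fibroblasts and matrix were higher in the aPD1 libraries by camera with its preset correlation (adjusted p = 0.397 with an estimated correlation for each). Among called genes with an average log2 CPM of at least 1 and no predicted-gene symbol, the largest rise was in H19, an imprinted noncoding RNA gene. It was at 725 ± 393 CPM with aPD1 and 29.5 ± 6.69 CPM with PBS (SD, n = 3 each; log2 fold change 4.62 ± 0.55 SE, adjusted p 0.0256). Dlk1, an imprinted gene of a preadipocyte surface factor, rose from 0.775 ± 0.209 to 17.3 ± 6.84 CPM, and Fhl1, a muscle LIM domain gene, from 9.32 ± 2.25 to 203 ± 65.6 CPM (adjusted p 0.0456 each). Cthrc1, a secreted collagen repeat gene, rose from 12.2 ± 2.52 to 255 ± 196 CPM, and Mfap5, a microfibril gene, from 31.5 ± 8.42 to 600 ± 380 CPM (adjusted p 0.0456 each). Itm2a rose from 15.6 ± 5.20 to 298 ± 120 CPM (0.0377), and C1qtnf3 (51.4 ± 18.4 to 645 ± 246 CPM) and Clec11a (7.46 ± 2.84 to 88.7 ± 18.6 CPM) had an adjusted p of 0.0256 each. Each of these 8 genes was higher in all 3 aPD1 libraries than in any PBS library, which the naming rule required. The 25 log2 fold changes ran from 1.82 for Pf4 to 6.43 for Gm36377. Among the called genes, 1500015O10Rik, H19, Ccn5 and Pf4 were higher with PZH against PBS too. Their log2 fold changes there were 2.41, 3.42, 2.79 and 1.81, without a call (edgeR adjusted p 0.0924 each). In aPD1 against PZH edgeR called 0 genes, so the rises are not shown to be particular to the antibody.

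The number of calls depended on the test and on single libraries. edgeR called 0 genes without any 1 of the 3 PBS libraries or without aPD1 replicate 2, and 2 genes without aPD1 replicate 1 or 3. DESeq2 called 2377 genes (1916 higher, 461 lower), limma-voom with sample weights 5801 (3130 higher, 2671 lower), and edgeR on the 6 libraries alone 691 (647 higher, 44 lower). edgeR without the low-count filter called 306 (296 higher, 10 lower), without the 3 libraries apart 1922 (1432 higher, 490 lower), and with the Y-linked covariate 3.

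Of the title's genes in aPD1 against PBS, Stat3 was at 144 ± 16.4 CPM (log2 fold change 0.78 ± 0.23, adjusted p 0.0924) and Cd274 at 65.3 ± 31.2 CPM (0.88 ± 0.58, adjusted p 0.333). DESeq2 (0.0133), limma-voom with sample weights (0.00349) and edgeR without the 3 libraries apart (0.0330) called Stat3, and limma-voom with sample weights called Cd274 (0.0365). In that fit aPD1 replicate 2, with the group's highest Cd274 (97.8 CPM), had a weight of 4.29. Replicates 1 and 3 had weights of 1.67 and 0.167, and the log2 fold change of Cd274 was 1.35. Over all alternatives the adjusted p ran from 0.00349 to 0.661 for Stat3 and from 0.0365 to 0.618 for Cd274. The Y-linked covariate lowered the log2 fold change of Stat3 to 0.24 (0.661). Cd44 was at 318 ± 126 CPM, Sox9 at 74.6 ± 57.3, Myc at 66.5 ± 45.9, Sox2 at 2.48 ± 2.33 CPM. Klf4 was at 109 ± 25.6 and Aldh1a1 at 116 ± 136 CPM, and none of these 6 was called by edgeR on all libraries (adjusted p from 0.0770 to 0.443). Aldh1a1 was called by DESeq2 (8.67e-05), limma-voom with sample weights (0.00574) and edgeR without the 3 libraries apart (0.0359). The Y-linked covariate lowered its log2 fold change from 4.53 to 0.96. The mean of Aldh1a1 rests on aPD1 replicate 3, with 273 CPM there and 34.3 and 40.3 CPM in the other 2 libraries. Sox9 (8.75 CPM), Myc (13.6), Cd44 (175) and Sox2 (0) were lowest in that library. In aPD1 replicates 1 and 2 Sox9 was at 101 and 113 CPM and Myc at 95.4 and 90.6 CPM. The log2 fold changes of Cd44, Sox9, Myc and Sox2 turned with the Y-linked covariate from -0.92, -1.53, -1.06 and -2.57 to 0.37, 1.42, 1.65 and 0.97. The covariate did not overlap between aPD1 and PBS libraries either, so values adjusted for it are extrapolations here too.

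Camera called 17 of the 31 lists in aPD1 against PBS (13 higher, 4 lower) and none with an estimated correlation. The skeletal muscle list had a median of 3.57, with 19 of 21 members passing adjusted over the list alone and 0 over all genes (camera adjusted p 1.02e-14; adjusted p = 0.397 with an estimated correlation). Its member Tnni2, a fast troponin gene, was at 256 ± 127 against 15.1 ± 14.3 CPM. The fibroblast and matrix list was higher (median 2.15, 17 higher and 1 lower of 26 adjusted over the list alone, 1 over all genes, camera adjusted p 1.98e-08; adjusted p = 0.397 with an estimated correlation). Pi16, a gene of adventitial fibroblasts, was at 253 ± 89.0 against 14.6 ± 3.97 CPM and Lox, a collagen crosslinking enzyme gene, at 408 ± 315 against 69.6 ± 25.7 CPM. The macrophage and monocyte list had a median of 1.57, with 14 of 25 adjusted over the list alone and 0 over all genes (camera adjusted p 1.23e-06; adjusted p = 0.397 with an estimated correlation), and Folr2, a gene of tissue-resident macrophages, was at 47.3 ± 52.0 against 1.89 ± 1.014 CPM. The interferon response list was positive in 34 of 35 members (median 0.71, 0 adjusted over the list alone and 0 over all genes, camera adjusted p 1.01e-05; adjusted p = 0.397 with an estimated correlation), with Irf9 at 91.8 ± 6.01 against 54.3 ± 6.73 CPM. The STAT3 list (median 0.50, camera adjusted p 0.0429; adjusted p = 0.505 with an estimated correlation) lost its call without PBS replicate 2 (0.0572), PBS replicate 3 (0.1), aPD1 replicate 1 (0.0639) or aPD1 replicate 2 (0.208), with the replicate as a block (0.06995) and with the Y-linked covariate (0.432). As with PZH, the checkpoint list was called higher (median 0.84, 7 of 19 adjusted over the list alone, camera adjusted p 0.000734). So were the T cell (0.87, camera adjusted p 0.000381) and neutrophil lists (2.05, 0.0174). The sterol (-1.54, 5.35e-08) and proliferation lists (-1.02, 7.08e-05) were called lower, again as with PZH. Their adjusted p with an estimated correlation ran from 0.397 to 0.614. Ddx3y was at 43.2 to 146 CPM with aPD1 and 11.9 to 29.6 CPM with PBS. With the Y-linked covariate 8 lists were called, the fibroblast (0.354) and macrophage (0.0585) calls ended and the proliferation list turned from lower to higher (3.56e-16).

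The comparison of PZH_aPD1 with PBS asks what both treatments together did. Muscle and fat cell genes and genes of antigen presentation were higher as groups in the combination libraries by camera with its preset correlation, and 1 gene rose. None of these lists was called with an estimated correlation (adjusted p 0.6997 each), and the fat cell list was not called without PZH_aPD1 replicate 3 (0.0937). The gene was 1500015O10Rik, which rose from 3.86 ± 0.931 to 38.3 ± 15.3 CPM (SD, n = 3 each; log2 fold change 3.31 ± 0.37 SE, edgeR adjusted p 0.0368). Cd274 was at 35.6 ± 16.2 CPM against 35.4 ± 11.96 with PBS (log2 fold change 0.01 ± 0.58, adjusted p 0.994), and Stat3 at 129 ± 32.4 CPM (0.62 ± 0.23, adjusted p 0.157), called by limma-voom with sample weights alone (0.009604). Those weights were 6.13, 0.695 and 0.213 for PZH_aPD1 replicates 1, 2 and 3. The Y-linked covariate lowered the log2 fold change of Stat3 to 0.22 (0.578, the highest adjusted p of its alternatives). The next 4 genes by p, Lmcd1, Tceal7, C1qtnf3 and Clec11a, had an adjusted p of 0.0553 each. C1qtnf3 was at 460 ± 194 against 51.4 ± 18.4 CPM and Lmcd1 at 15.1 ± 7.24 against 1.35 ± 0.469 CPM. edgeR had 3749 genes at an unadjusted p under 0.05, DESeq2 called 1920 (1559 higher, 361 lower), and limma-voom with sample weights 4885 (2529 higher, 2356 lower). edgeR without the low-count filter called 215, edgeR with DESeq2's size factors 13 and edgeR with the Y-linked covariate 4. Without the 3 libraries apart edgeR called 1 gene, which was not 1500015O10Rik (0.0526). It called 0 genes on the 6 libraries alone, and 0 without any 1 of the PBS libraries or PZH_aPD1 replicate 1 or 3. It called 874 (827 higher, 47 lower) without PZH_aPD1 replicate 2.

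Of the stem cell genes in the combination libraries, Cd44 was at 296 ± 160 CPM, Sox9 at 84.3 ± 68.5, Myc at 73.0 ± 56.2, Sox2 at 4.46 ± 3.91 CPM. Klf4 was at 140 ± 10.1 and Aldh1a1 at 67.6 ± 69.7 CPM (43.9, 12.9 and 146 CPM in the 3 libraries), with none of the 6 called against PBS by edgeR (adjusted p from 0.105 to 0.562). Without PZH_aPD1 replicate 2 Aldh1a1 was called (0.0419), and without PZH_aPD1 replicate 3 its adjusted p was 0.408. DESeq2 (0.00176) and limma-voom with sample weights (0.00816) called it too. The Y-linked covariate lowered its log2 fold change from 3.76 to 1.24. Sox9 (5.55 CPM), Myc (11.2), Cd44 (111) and Sox2 (0.177) were lowest in PZH_aPD1 replicate 3. In PZH_aPD1 replicates 1 and 2 Sox9 was at 117 and 130 CPM and Myc at 86.8 and 121 CPM. The log2 fold changes of Sox9, Myc and Sox2 against PBS turned with the Y-linked covariate from -1.35, -0.93 and -1.74 to 0.21, 0.64 and 0.34. Camera called 15 lists (11 higher, 4 lower) and none with an estimated correlation, and 0 list members passed over all genes. The skeletal muscle list had a median of 4.39, with 21 of 21 adjusted over the list alone (camera adjusted p 6.14e-22; adjusted p = 0.6997 with an estimated correlation), and Mb was at 146 ± 90.4 against 7.23 ± 3.18 CPM. The adipocyte list was positive in 16 of 16 members (median 3.46, 0 adjusted over the list alone, camera adjusted p 0.000391; adjusted p = 0.6997 with an estimated correlation). Plin1, a lipid droplet gene, was at 75.4 ± 115 against 2.20 ± 3.08 CPM, with 207 CPM in PZH_aPD1 replicate 3, without which the list was not called (0.0937). The antigen presentation list was higher (median 0.63, 7 of 23 adjusted over the list alone, camera adjusted p 0.000107; adjusted p = 0.6997 with an estimated correlation), with H2-T23 at 339 ± 146 against 103 ± 8.54 CPM and H2-DMa at 156 ± 90.4 against 34.9 ± 13.5 CPM. The checkpoint (median 0.58, camera adjusted p 0.00996) and T cell lists (0.85, 0.000309) were called higher here too. Sterol (-1.10, 0.000107) and proliferation lists (-0.50, 0.000391) were called lower, and the neutrophil list was not called (0.34, 0.272). Ddx3y was at 24.6 to 98.8 CPM with both treatments. With the Y-linked covariate 5 lists were called and the adipocyte list turned lower without a call (0.311).

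**Figure D3:**
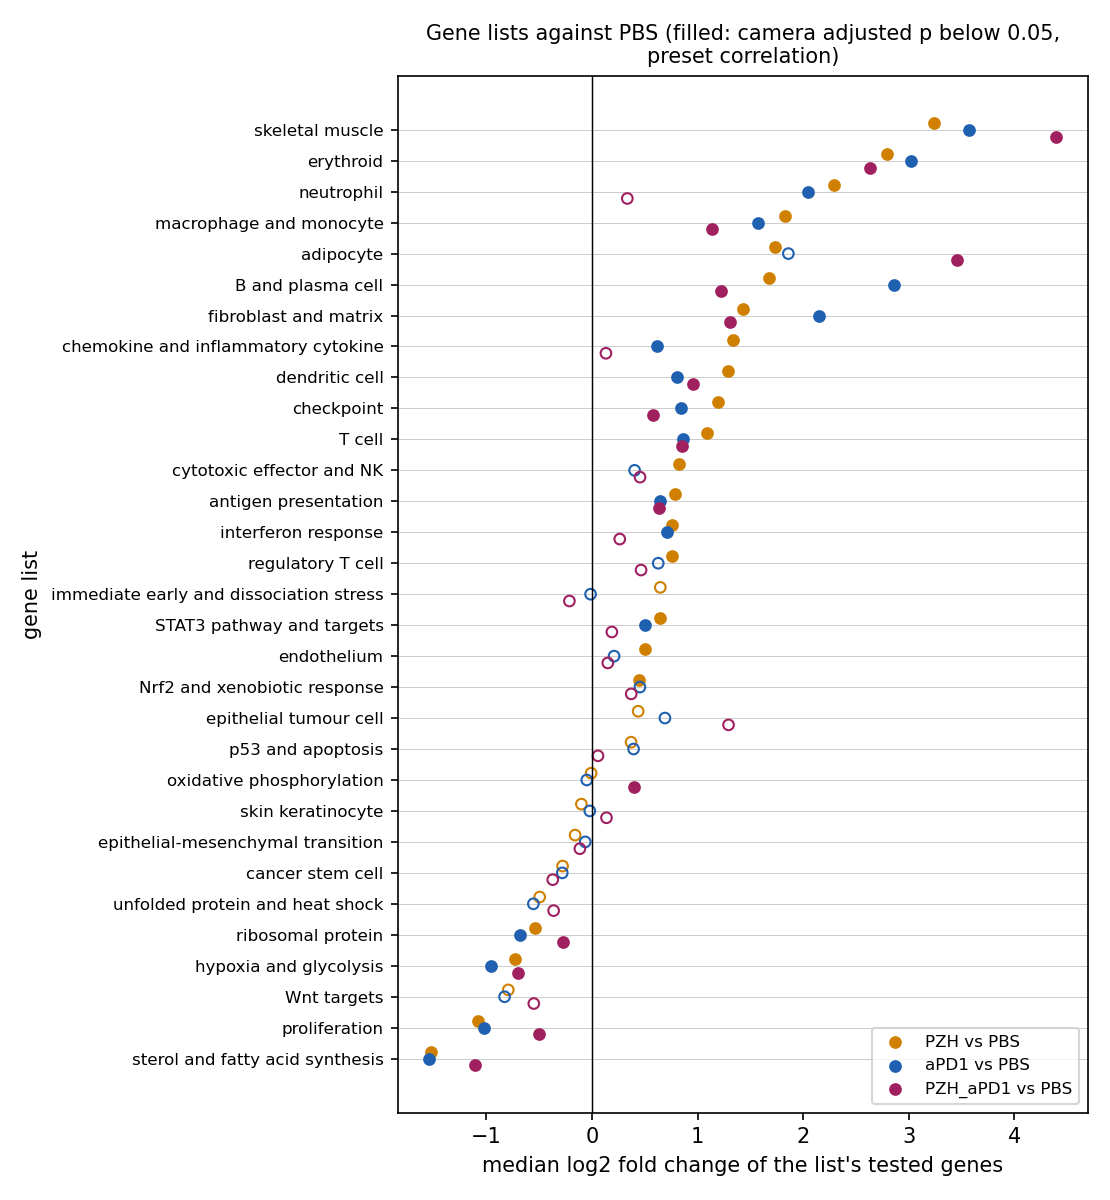
Median log2 fold change against PBS (x axis) of the tested members of 31 gene lists (y axis) for PZH, aPD1 and PZH_aPD1; filled points passed camera with its preset correlation (adjusted p under 0.05) and open points did not. Skeletal muscle genes lie highest in all 3 comparisons, at 3.24, 3.57 and 4.39, and no list passed with an estimated correlation.

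The comparison of PZH_aPD1 with aPD1 asks what PZH added to the antibody. No single gene passed, and as groups genes of the interferon response and of matrix were lower and genes of oxidative phosphorylation and fat cells were higher with the combination, by camera with its preset correlation. With an estimated correlation their adjusted p was 0.457, 0.542, 0.417 and 0.588, and the fat cell list turned direction without PZH_aPD1 replicate 3 (0.362). edgeR called 0 genes, with 185 at an unadjusted p under 0.05 (844 expected by chance), and DESeq2 and limma-voom with sample weights called 0 and 0. The counts in the 3 comparisons among treated groups (185, 265 and 171) fell far under 844. Their p-values were therefore not evenly spread, so 844 is a rough benchmark and the calls of 0 genes may be conservative. Cd274 was at 35.6 ± 16.2 CPM with the combination and 65.3 ± 31.2 CPM with aPD1 (SD, n = 3 each; log2 fold change -0.87 ± 0.58 SE) and Stat3 at 129 ± 32.4 and 144 ± 16.4 CPM (-0.17 ± 0.23), each with an adjusted p of 0.999. The smallest p values belonged to Gm43071, Rgcc, Nos3, Cxcr2 and Ifi44 (adjusted p 0.999). Rgcc, a cell cycle regulator gene, was at 45.01 ± 20.2 against 17.8 ± 1.61 CPM and Nos3, the endothelial nitric oxide synthase gene, at 2.34 ± 0.145 against 0.967 ± 0.229 CPM.

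Camera called 13 lists in PZH_aPD1 against aPD1 (6 higher, 7 lower) and none with an estimated correlation, and 0 members of any list passed over all genes or adjusted over the list alone. The interferon response list was negative in 33 of 35 members (median -0.41, camera adjusted p 2.14e-09; adjusted p = 0.457 with an estimated correlation), with Ifi44 at 22.2 ± 3.97 against 41.4 ± 5.92 CPM and Ifit1 at 43.0 ± 17.2 against 85.8 ± 38.1 CPM. The oxidative phosphorylation list was positive in 24 of 24 members (median 0.35, camera adjusted p 3.66e-11; adjusted p = 0.417 with an estimated correlation), with Ndufb8, a gene of respiratory complex I, at 119 ± 16.6 against 76.5 ± 21.9 CPM. The fibroblast and matrix list had a median of -0.56 (camera adjusted p 6.57e-08; adjusted p = 0.542 with an estimated correlation). The adipocyte list had a median of 1.64 (camera adjusted p 5.99e-05; adjusted p = 0.588 with an estimated correlation) and lost its call without aPD1 replicate 1 (0.0785), aPD1 replicate 2 (0.0780) or PZH_aPD1 replicate 3 (0.362, with the direction turned). Plin1 stood at 207 CPM in PZH_aPD1 replicate 3. The skeletal muscle list was called higher (median 0.68, camera adjusted p 0.00216; adjusted p = 0.756 with an estimated correlation), but not without aPD1 replicate 3 (0.645), PZH_aPD1 replicate 1 (0.540) or PZH_aPD1 replicate 3 (0.573), and it turned lower without the 3 libraries apart (0.219). The B and plasma cell list was called lower (median -0.96, camera adjusted p 0.00107; adjusted p = 0.588 with an estimated correlation), but not without PZH_aPD1 replicate 2 (0.173), and it turned direction without aPD1 replicate 3 (0.615) and with the Y-linked covariate (0.816). Ddx3y was at 24.6 to 98.8 CPM with both treatments and 43.2 to 146 CPM with aPD1.

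The comparison of PZH_aPD1 with PZH asks what the antibody added to PZH. Neutrophil, chemokine, interferon and STAT3 pathway genes were lower as groups with the combination than with PZH alone, and genes of oxidative phosphorylation were higher, while no single gene passed. These are calls of camera with its preset correlation, and with an estimated correlation their adjusted p ran from 0.0853 to 0.0880. Cd274 was at 35.6 ± 16.2 CPM with the combination and 119 ± 72.6 CPM with PZH (SD, n = 3 each; log2 fold change -1.74 ± 0.59 SE, edgeR adjusted p 1.000) and Stat3 at 129 ± 32.4 and 170 ± 28.8 CPM (-0.40 ± 0.23, adjusted p 1.000). edgeR called 0 genes, with 265 at an unadjusted p under 0.05 (844 expected by chance), DESeq2 called 2 and limma-voom with sample weights 1, all lower. The smallest p values belonged to Cxcr2, Hdc, Gm43071, XLOC_023191 and Slfn4. Cxcr2 was at 1.07 ± 0.581 against 7.15 ± 3.43 CPM, Hdc, the gene of the enzyme that makes histamine, at 2.74 ± 0.487 against 10.5 ± 5.19 CPM, and Slfn4, a myeloid gene of the Schlafen family, at 10.9 ± 3.34 against 49.4 ± 29.9 CPM.

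Camera called 19 lists in PZH_aPD1 against PZH (5 higher, 14 lower) and none with an estimated correlation, where the smallest adjusted p was 0.0853, and 0 members passed over all genes. The neutrophil list had a median of -1.28 and 1 of 19 members, Cxcr2, passing adjusted over the list alone (camera adjusted p 2.71e-16; adjusted p = 0.0853 with an estimated correlation). Cxcl2, a neutrophil-attracting chemokine gene, was at 12.4 ± 10.99 against 66.4 ± 31.3 CPM and Mmp9, a matrix protease gene, at 14.4 ± 0.120 against 31.5 ± 14.1 CPM. The interferon response list was negative in 35 of 35 members (median -0.53, 0 adjusted over the list alone, camera adjusted p 4.75e-18; adjusted p = 0.0853 with an estimated correlation), with Rsad2 at 19.3 ± 3.38 against 38.0 ± 19.4 CPM. The STAT3 list was negative in 28 of 31 members (median -0.44, 0 adjusted over the list alone, camera adjusted p 2.22e-11; adjusted p = 0.0853 with an estimated correlation), with Il6 at 1.25 ± 0.434 against 3.91 ± 4.17 CPM. The chemokine and inflammatory cytokine list (median -0.78, camera adjusted p 1.45e-12) and the oxidative phosphorylation list (median 0.39, camera adjusted p 3.08e-12) each had an adjusted p = 0.0880 with an estimated correlation. The skeletal muscle list was positive in 21 of 21 members (median 1.03, 0 adjusted over the list alone, camera adjusted p 7.32e-10; adjusted p = 0.359 with an estimated correlation) and lost its call without PZH replicate 1 (0.0753). The adipocyte list was positive in 16 of 16 (median 1.76, 0 adjusted over the list alone, camera adjusted p 6.91e-05; adjusted p = 0.420 with an estimated correlation) and turned direction without PZH_aPD1 replicate 3 (0.0629) and without the 3 libraries apart (0.467). The immediate early and dissociation stress list was called lower too, with 17 of 18 members negative (median -0.83, camera adjusted p 7.31e-10). Its adjusted p was 0.223 with an estimated correlation. Ddx3y was at 24.6 to 98.8 CPM with both treatments and 46.5 to 90.3 CPM with PZH. The number of lists called fell to 11 without PZH replicate 2.

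The single treatments were also compared with each other, aPD1 against PZH. No gene passed, and as groups neutrophil and immediate early genes were lower and matrix genes higher with aPD1, by camera with its preset correlation. Each of these lists had an adjusted p = 0.902 with an estimated correlation, and the immediate early list turned higher without PZH replicate 2 (0.835) and without the 3 libraries apart (0.000661). edgeR called 0 genes, with 171 at an unadjusted p under 0.05 (844 expected by chance), and DESeq2 and limma-voom with sample weights called 0 and 0. Cd274 had a log2 fold change of -0.86 ± 0.58 and Stat3 of -0.23 ± 0.23 (SE, adjusted p 1.000 each). Camera called 11 lists (3 higher, 8 lower) and none with an estimated correlation, with 0 members passing over all genes or adjusted over the list alone. The neutrophil list had a median of -0.77 (camera adjusted p 2.35e-05; adjusted p = 0.902 with an estimated correlation) and lost its call without PZH replicate 2 (0.385) or aPD1 replicate 1 (0.11). Its members went both ways, with Cxcl2 at 17.6 ± 14.0 against 66.4 ± 31.3 CPM and Retnlg at 19.3 ± 26.5 against 4.65 ± 3.54 CPM (n = 3 each), and without aPD1 replicate 3 the log2 fold change of Retnlg turned from 2.05 to -0.21. The immediate early list had a median of -0.76 (camera adjusted p 1.90e-05; adjusted p = 0.902 with an estimated correlation). The fibroblast and matrix list had a median of 0.60 (camera adjusted p 3.66e-05; adjusted p = 0.902 with an estimated correlation), with Col6a1 at 494 ± 268 against 267 ± 18.0 CPM, and it lost its call without aPD1 replicate 3 (0.451). Without the 3 libraries apart camera called 13 lists (10 higher, 3 lower), 7 of them shared with the 11, so most directions were then upward. Without PZH replicate 1 it called 17 lists, and without aPD1 replicate 1 it called 5.

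The interaction tests whether the effect of PZH differs with and without the antibody, as the change from aPD1 to PZH_aPD1 minus the change from PBS to PZH. Interferon, macrophage, neutrophil, matrix and muscle genes had negative interactions as groups by camera with its preset correlation. None of these calls was kept with an estimated correlation (smallest adjusted p 0.270). The same lists were higher with PZH against PBS. With PZH added to aPD1, the interferon (median -0.41), neutrophil (-0.50) and matrix (-0.56) lists were called lower. The macrophage list was not called (-0.11), and the muscle list was called higher (0.68). PBS enters the contrast with a plus sign. PBS libraries that differ alike from all 3 treated groups would therefore also give negative interactions for lists raised by each treatment. edgeR called 0 genes, with 2525 at an unadjusted p under 0.05 and a smallest adjusted p of 0.264. DESeq2 called 496 (53 positive, 443 negative), limma-voom with sample weights 2187 (559 positive, 1628 negative). edgeR without the 3 libraries apart called 117 (12 positive, 105 negative) and edgeR with the Y-linked covariate 1. Camera called 23 lists (18 negative, 5 positive) and none with an estimated correlation, where the smallest adjusted p was 0.270. The interferon response list had a median of -1.20 with 34 of 35 members negative and 10 passing adjusted over the list alone (camera adjusted p 1.24e-11; adjusted p = 0.270 with an estimated correlation). The sterol and fatty acid synthesis list had a median of 1.995 with 5 of 23 (camera adjusted p 2.35e-10; adjusted p = 0.270 with an estimated correlation). With the Y-linked covariate 14 lists were called, the sterol call ended (0.274) and the proliferation list (median 1.52, camera adjusted p 3.31e-05; adjusted p = 0.550 with an estimated correlation) turned negative (8.69e-18).

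A test for any difference among the 4 groups called 0 genes by edgeR, with 2713 at an unadjusted p under 0.05 and a smallest adjusted p of 0.157. DESeq2 called 1519 genes, limma-voom with sample weights 3702, edgeR without the low-count filter 25, edgeR without the 3 libraries apart 225, and edgeR without PZH_aPD1 replicate 2 called 18.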

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

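The tests of the 2 patterns below were chosen after the results were seen, while the interaction tests and the counts over other splits of the libraries were planned.

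The first set of results concerns a difference between groups: the interaction of PZH with the antibody was called in 23 gene lists (18 negative, 5 positive) by camera with its preset correlation. None of the 23 passed with an estimated correlation (smallest adjusted p 0.270), and chance is not excluded, since 4 of 46 splits of the libraries into 4 groups called as many lists (23 in the real split and 23 in the highest other). The negative medians of log2 interaction were -3.34 for the erythroid, -2.95 for the B and plasma cell, -2.81 for the neutrophil, -2.50 for the skeletal muscle, -2.35 for the fibroblast and matrix, -1.94 for the chemokine and inflammatory cytokine and -1.93 for the macrophage and monocyte lists. They were -1.68 for the dendritic cell, -1.36 for the checkpoint, -1.20 for the interferon response, -1.12 for the T cell, -1.07 for the regulatory T cell and -1 for the cytotoxic effector and NK lists. They were -0.99 for the antigen presentation, -0.99 for the STAT3, -0.64 for the Nrf2, -0.61 for the immediate early and -0.61 for the endothelium lists. Positive medians were 0.38 for oxidative phosphorylation, 0.97 for ribosomal protein, 1.07 for hypoxia and glycolysis, 1.52 for proliferation and 2 for sterol and fatty acid synthesis genes.

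The first pattern weighed is that lists of host cells were higher in the 9 treated libraries than in the 3 PBS libraries. The skeletal muscle score was higher by 3.41 (9 of 9 treated libraries above all PBS libraries, exact permutation p 0.00455, the smallest that 220 splits can give) and the Y-linked score by 1.78 (8 of 9, exact p 0.0136). A lower share of MC38 cells alone would raise markers found only in other cells alike. Muscle exceeded endothelium by 3.07 (8 of 9, exact p 0.00909, 0.0455 adjusted over 10 tests). The pair was picked after the values were seen, with muscle the highest list against PBS and endothelium low (medians 0.50, 0.21 and 0.15). No label or table shows that MC38 cells lack these transcripts either. The gap therefore cannot decide, and a lower share of MC38 cells alone stays open. More muscle from around the tumour in the treated samples (muscle minus Y-linked score 1.63, exact p 0.127) and T cells entering the treated tumours (T cell minus Y-linked score -0.707, exact p 0.191, while the T cell score alone was higher by 1.07, exact p 0.0273, 0.0682 adjusted over 10 tests) stay open, because these differences were within the spread of the 12 libraries. A treatment that shrinks the tumour and so brings more surrounding tissue into a sample was not tested, since no label gives tumour size.

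The second pattern is that PZH replicate 2, aPD1 replicate 3 and PZH_aPD1 replicate 3 lay apart on the first principal component. Library size is argued against, since the gap to the next library was 52.8 after all libraries were thinned to the lowest total (54.5 before), against an SD of 21.5 among the other libraries. Few MC38 cells in those samples may be the cause and stays open: 3 of 3 had the highest Y-linked score of their own group, but those genes were chosen after their values were seen, and no label or table shows that MC38 cells lack Y-linked transcripts. The treatments stay open too: 3 of 9 treated and 0 of 3 PBS libraries lay apart, and with 3 libraries apart Fisher's exact test (p 0.509) could not have passed for an excess among treated libraries, so it decides nothing about them.

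The splits of the 6 libraries of a comparison number 10, the real one included, too few for a share under 0.05. The real and the highest other number of genes called by edgeR were 25 and 0 in aPD1 against PBS, 1 and 0 in PZH_aPD1 against PBS, and 0 and 0 in PZH against PBS and in the 3 comparisons among treated groups, whose counts at an unadjusted p under 0.05 and by other tools stand in the report. For lists they were 22 and 23 in PZH against PBS, 17 and 19 in aPD1 against PBS, 15 and 18 in PZH_aPD1 against PBS, 13 and 12 in PZH_aPD1 against aPD1, 19 and 21 in PZH_aPD1 against PZH, and 11 and 19 in aPD1 against PZH. For the interaction and for any group edgeR called 0 genes in the real split and at most 0 in the others. With a real count of 0 all 46 of 46 splits give as many by construction, so these splits say nothing about chance (unadjusted p under 0.05 in 2525 and 2713 genes, and 496 and 1519 genes called by DESeq2).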

How the results depend on the processing

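The fit without the 3 libraries apart and the fit with the Y-linked covariate were chosen after the data were seen, and the other alternatives were planned. Of 120 list calls, over all alternatives together, 1121 outcomes kept direction and call, 298 kept direction and lost the call and 39 turned direction. Of 141 named gene results, 1544 outcomes kept direction and side of the threshold, 242 gained a call, 60 lost it and 17 turned. Of the numbers of genes called, 89 stayed within 1.5 times and 41 moved. Of the numbers of lists called, 69 stayed and 14 moved. Where no cause is given below, the cause was not tested.

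Numbers of genes called are given in the order PZH, aPD1 and PZH_aPD1 against PBS where 3 stand together, and were 0, 25 and 1 by edgeR. DESeq2, which made 56 false calls against 7 by edgeR in the simulation of PZH against PBS, called 2020, 2377 and 1920. It called 2 in PZH_aPD1 against PZH, 496 for the interaction and 1519 for any group. limma-voom with sample weights called 2153, 5801 and 4885, with 1, 2187 and 3702 in the same further tests. No low-count filter gave 339, 306 and 215, with 25 for any group. DESeq2's size factors gave 13 in PZH_aPD1 against PBS. Only the 6 libraries compared gave 691 in aPD1 against PBS and 0 in PZH_aPD1 against PBS. The replicate block gave 3 in aPD1 against PBS and turned Cd274 in PZH_aPD1 against PBS from 0.01 to -0.0365, though the replicate numbers do not pair the libraries (same-number pairs had r from -0.737 to 0.719, and 5 of 12 libraries correlated best with their own number). Leaving out the 3 libraries apart gave 950 in PZH against PBS, 1922 in aPD1 against PBS, 117 for the interaction and 225 for any group, and in PZH_aPD1 against PBS 1 gene, 0 shared with edgeR on all libraries. The Y-linked covariate gave 3 in aPD1 against PBS, 4 in PZH_aPD1 against PBS and 1 for the interaction. A fold minimum of 2 changed no number.

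Leaving out each replicate in turn gave 0 to 1 genes in PZH against PBS (1 without PZH replicate 3), 0 to 2 in aPD1 against PBS (0 without PBS replicate 1, 2 or 3 or aPD1 replicate 2), 0 to 874 in PZH_aPD1 against PBS (874 without PZH_aPD1 replicate 2) and 0 to 18 for any group (18 without PZH_aPD1 replicate 2). List calls ranged from 11 (without PZH replicate 2) to 22 in PZH_aPD1 against PZH and from 5 (without aPD1 replicate 1) to 17 (without PZH replicate 1) in aPD1 against PZH. Adjusted p of lists that turned direction ranged, in PZH_aPD1 against aPD1, from 9.52e-05 to 0.615 for B and plasma cells, 2.19e-18 to 0.362 for adipocytes and 1.46e-06 to 0.743 for hypoxia and glycolysis. In PZH_aPD1 against PZH they ranged from 2.80e-06 to 0.686 for the cytotoxic, 9.065e-07 to 0.4495 for the antigen presentation and 3.02e-17 to 0.0629 for the adipocyte list. In aPD1 against PZH they ranged from 6.09e-08 to 0.815 for antigen presentation, 6.24e-06 to 0.649 for macrophages, 9.61e-10 to 0.814 for muscle, 1.13e-06 to 0.985 for erythroid, 5.60e-05 to 0.251 for hypoxia and glycolysis, 6.24e-06 to 0.762 for chemokine and 5.06e-12 to 0.835 for immediate early genes. The log2 fold change of Cd274 in PZH_aPD1 against PBS ranged from -0.28 to 0.35, and that of Retnlg in aPD1 against PZH from -0.21 to 2.87.

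Camera with an estimated correlation called 0 lists in each of the 7 contrasts (PZH vs PBS 0, aPD1 vs PBS 0, PZH_aPD1 vs PBS 0, PZH_aPD1 vs aPD1 0, PZH_aPD1 vs PZH 0, aPD1 vs PZH 0, interaction 0).

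With the Y-linked covariate 11, 8 and 5 lists were called in PZH, aPD1 and PZH_aPD1 against PBS and 14 for the interaction. The covariate did not overlap between PBS and either single treatment, so ended calls and turned directions there are extrapolations. Lists that turned direction had an adjusted p, in PZH against PBS, of 0.2554 for B and plasma cells, 0.4994 for fibroblasts and matrix, 3.71e-08 for adipocytes, 1.02e-10 for proliferation and 0.0001255 for hypoxia and glycolysis. In aPD1 against PBS it was 0.4998 for B and plasma cells, 3.56e-16 for proliferation and 0.01375 for hypoxia and glycolysis. In PZH_aPD1 against PBS it was 0.5776 for B and plasma cells, 0.3115 for adipocytes, 2.805e-05 for proliferation and 0.3115 for hypoxia and glycolysis. In PZH_aPD1 against aPD1 it was 0.816 for B and plasma cells and 0.0243 for hypoxia and glycolysis. For the interaction it was 0.329 for B and plasma cells, 8.69e-18 for proliferation and 2.53e-05 for hypoxia and glycolysis. Log2 fold changes against PBS turned to 1.29 (Sox9), 1.44 (Sox2), 0.39 (Cd44) and 1.54 (Myc) with PZH, to 1.42 (Sox9), 0.97 (Sox2), 0.37 (Cd44) and 1.65 (Myc) with aPD1, and to 0.21 (Sox9), 0.34 (Sox2) and 0.64 (Myc) with PZH_aPD1.

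Without the 3 libraries apart, lists that turned direction had an adjusted p of 0.219 for muscle in PZH_aPD1 against aPD1, 0.137 for cytotoxic and 0.467 for adipocyte in PZH_aPD1 against PZH, and, in aPD1 against PZH, 0.938 for STAT3, 0.00126 for antigen presentation, 0.178 for macrophage, 0.108 for chemokine and 0.000661 for immediate early genes.

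The calls of the skeletal muscle, macrophage, neutrophil, T cell, checkpoint, STAT3, proliferation, sterol and interferon lists in PZH against PBS held without each single library. The effect of sequencing depth on the calls was not tested beyond the thinned first component.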

Other observations

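The tests in this part were chosen after the results were seen.

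Genes of liver cells, which no comparison of the report describes, were present in some tumour libraries. Alb, the gene of serum albumin, ran from 0.170 CPM in PBS replicate 1 to 523 CPM in PZH replicate 2, and was at 94.6 CPM in PBS replicate 3 and 234 CPM in aPD1 replicate 1. Mup3, a gene of a major urinary protein made in liver, was at 120 CPM in PZH replicate 2, 43.2 CPM in aPD1 replicate 1 and 24.9 CPM in PBS replicate 3, and Serpina3k, a protease inhibitor gene, at 93.6, 34.2 and 22.8 CPM in the same libraries.

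The third pattern weighed is these hepatocyte transcripts. The treatments stay open as a cause: the hepatocyte score ranged by up to 5.77 log2 within a group and the 4 group means by 3.81, but single libraries spread more than means of 3 in any case, so this decides nothing. Whether 1 hepatocyte RNA source in different amounts or several sources gave them stays open. Across 31 hepatocyte genes, the 8 libraries with Alb of at least 20 CPM included 7 that correlated with the library of highest Alb at r 0.828 to 0.979, which several liver sources with similar profiles would give as well. No label says whether liver was handled beside the tumours.

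A hypothesis of this re-analysis is that Cd274, which interferon can induce, follows the interferon response of each library. Over the 9 libraries that do not stand apart, Cd274 went with the mean of the 35 interferon response genes at Pearson r 0.873 (exact permutation p 0.000747, 0.00149 adjusted over 2 relations) and Spearman rho 0.933 (exact p 0.00075). It was 0.842 over the 7 libraries left without the 2 farthest, and 0.811 for deviations from group means. The relation of Cd274 to the neutrophil score was weaker (Pearson r 0.714, exact p 0.0345; rho 0.533, exact p 0.148) and rested on 2 libraries, without which r was 0.390. A shared dependence on how many host cells a library holds was not removed, so the hypothesis may still reflect cell makeup.

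Xist, the noncoding RNA of the inactive X chromosome, had 0 to 6 counts in every library. Pdcd1, the gene of PD-1 itself, was at 9.49 ± 5.18 CPM with PBS, 14.1 ± 9.07 with PZH, 10.8 ± 7.02 with aPD1 and 14.2 ± 2.89 with both (SD, n = 3 each).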
